A study of Mus musculus with 34 samples.

How the data were processed

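Tumours were digested with a GentleMACS, CD45-positive or CD4/8-positive cells were extracted magnetically, and libraries were made with a Chromium Single Cell 3' kit. The deposited matrices hold whole-number UMI counts per feature and barcode from Cell Ranger 6.0.0, per the file headers, against GRCm38/mm10, with barcodes already called as cells. The pooled tumour table holds counts that the authors made with Cell Ranger and merged with Seurat, and their versions are not given in the sources used here. Its cell names show 2 barcode sets of 1508 and 2508 cells without saying which tumour each came from, so no tumour was compared with another. A bulk expression table of the tumour line has 12 columns whose names match no sample, so its contrasts of doxorubicin and interferon-gamma were not run. The 10 ATAC samples were not analysed here.

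The sorted-cell matrices carry no gene names. The plan fixed before the data were examined was to treat their rows as unnamed unless a file named them. Names were then taken from the pooled table of the same series, which has 32285 genes in the same number of rows. Row totals correlated with the pooled table at r of 0.954 to 0.984 in the same row and at most 0.354 when shifted by up to 50 rows. In all 3070 of 3070 windows of rows the unshifted match was best. These correlations are across genes, which are not independent replicates.

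Choices made before the data were examined were the filters, the tests of the whole immune libraries, 25 gene lists, the cell type markers and the main alternatives. Tests within cell classes, the background filter, the class naming score, 7 further lists of T cell and macrophage genes and the class comparisons were chosen later. The rule that names genes in the immune and T cell comparisons was written once the matrices were found usable and before any expression value was seen. Cells with 500 or more UMIs, 200 or more genes and under 20% mitochondrial UMIs were kept, which left 1480 to 3996 cells per immune library and 3445 to 7623 per T cell library. In Python 3.11.15, scanpy 1.11.5 took 2000 variable genes, 30 principal components and 15 neighbours, and clustered all sorted libraries jointly with Leiden at resolution 1 (igraph 0.11.9, numpy 2.4.6, pandas 2.3.3, scikit-learn 1.9.0). Markers of 14 classes gave each cluster a score, scaled to each gene's highest cluster. A class name needed a score of 0.25, at least 3 markers detected in 20% or more of cells, and no more of the cluster's 10 top genes from another class. This rule was revised once after the leading genes of the clusters had been seen. Of 26 clusters, 21 were named. Clusters 2, with Gm26917, Lars2 and low UMIs, and 4, with haemoglobin genes, stayed unnamed beside clusters 5, 12 and 17. Cluster 2 made up 0.400 to 1.45% and cluster 4 0.125 to 0.307% of the immune libraries, and they made up 0.249 to 3.33% and 0.417 to 3.62% of the T cell libraries. A doublet caller marked at most 0.167% of any sorted library, too few to have worked, and 46 cells (1.15%) of the pooled table, which were removed.

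Counts were summed per class and library, with at least 30 cells per class and library, and tested with edgeR 4.0.16 in R 4.3.3 (TMM, filterByExpr, robust quasi-likelihood F test, two-sided). P values were adjusted by Benjamini-Hochberg over the genes tested and called at 0.05. Within a class, genes were tested only where the class held at least 0.1 of the level of the highest class, to limit RNA from other cells. Each list with 4 or more measured genes was tested with limma 3.58.1 camera at a preset correlation of 0.01 and adjusted over the lists of a comparison. No list call held with an estimated correlation. Named genes were Cd274 and Cd80, Pdcd1 and Ctla4 in T cells, the 6 largest rises and 4 largest falls among called genes at a mean of 20 CPM (counts scaled to library size) or more with groups that did not overlap, and 3 members with the smallest adjusted p of each called list, of which some are not reported here. Log2 changes in the text are edgeR's, so a value for a gene with few counts depends on its prior count. RLE and DESeq2 scaling moved the median gene by at most 0.03 log2.

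On counts with simulated changes of 2 log2 units, the same fit recovered 59.6% of changed genes in the whole library, 54.5% in neutrophil-like, 79.8% in macrophage- or monocyte-like, 92% in T cell-like and 90.9% in epithelial-like cells. At 1 log2 unit it recovered 4.26, 5.26, 26, 27 and 15.5%. Of the calls it made, 19.2, 11.9, 25, 8.46 and 18.0% were genes left unchanged, above the 5% aimed for with 2 against 2 libraries. This was 1 simulated run per comparison, with 94 to 100 tested genes given each size of change and all others none. The real data may hold more changed genes, so these rates may not carry over.

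With 1 library per group, T cell values are UMIs per 10000 of the class with exact Poisson intervals and exact intervals of ratios at 95% confidence, computed with scipy 1.17.1, and no p. Genes with 200 or more UMIs over both libraries gave the 6 highest and 6 lowest ratios. List medians used members with 20 or more UMIs and a pseudocount of 0.5, against 10000 random lists. In these, each member was replaced by a gene within 50 places of it in rank of mean level. Shares of cells use exact Clopper-Pearson intervals. Thinning drew 2000 UMIs per cell and left out 28 to 113 cells per library with fewer. All intervals cover counting error only. Alternatives were RLE scaling, DESeq2 1.42.0, no low count filter, no background filter, a strict cell filter (1000 UMIs, 10% mitochondrial), removal of the 5% of cells with most UMIs, Leiden resolutions of 0.5 and 2, replicate number as a block, cluster 12 in the T cell class, and each library left out. Figures were drawn with matplotlib 3.10.9.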

Results

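MMTV-Wnt1 tumours are mouse mammary tumours driven by the Wnt1 oncogene, and doxorubicin is a chemotherapy drug that damages DNA. The series carried such tumours in C57BL6j mice and collected them untreated or after 5 consecutive doses of 4 mg/kg doxorubicin. Of its 34 samples, 10 single-cell RNA libraries are compared here. Of these, 4 held CD45-positive immune cells, with 2 untreated libraries and 2 taken 48 h after the last doxorubicin dose. The other 6 held CD4/8-positive T cells, 1 library per group. These groups were untreated, 48 h after doxorubicin, and doxorubicin followed by 3 doses, 72 h apart, of IgG control antibody, anti-PD1, anti-CTLA4 or both antibodies, harvested 24 h after the last dose. Single antibodies were given at 200 ug with 200 ug IgG, both together at 200 ug each, and the control at 400 ug IgG. PD1 and CTLA4 are inhibitory receptors of T cells, and the antibodies against them are the usual form of immune checkpoint blockade. Both kinds of cell were extracted magnetically from digested tumours. A further table pooled 4016 tumour single cells of 2 barcode sets. The immune libraries held 69.1 and 36.6 M UMIs untreated and 16.9 and 35.2 M after doxorubicin, with medians of 9138.5 and 7377 against 5341 and 3873.5 UMIs per barcode. The T cell libraries held 47.8 to 93.7 M UMIs, with medians of 5901 to 10065 per barcode. The labels do not state whether replicates were separate animals, and the T cell libraries have no replicates, so their intervals cover counting error only.

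The first comparison asks which cells made up the CD45-sorted immune compartment of the tumours before and after doxorubicin. Neutrophil-like cells, short-lived granulocytes marked by S100a8, S100a9 and Retnlg, were the most abundant named class after doxorubicin. They made up 60.6% (exact Clopper-Pearson interval 58.1 to 63.1%) and 55.2% (53.7 to 56.8%) of cells after doxorubicin, and 10.9% (9.94 to 12%) and 7.79% (6.59 to 9.13%) of untreated cells. The group means were 57.9% ± 3.82 and 9.37% ± 2.23 (SD, n = 2 each), a difference of 48.5 points, many times the spread between replicates. The two-sided exact permutation p was 0.333, the smallest that 2 against 2 libraries can give. Macrophage- or monocyte-like cells, marked by C1qa, Csf1r and Adgre1, made up 14.4 and 44.5% untreated and 18.1 and 18.4% after doxorubicin, so the untreated libraries lay on both sides. The class leaves out the unnamed cluster 5 described below, whose nearest class by marker score was dendritic cells. With that cluster counted in, both untreated libraries would lie above both doxorubicin ones. Whether the share of such cells differed thus depends on how the cluster is counted. T cell-like cells were 20.5 and 8.40% untreated and 6.15 and 7.58% after doxorubicin. NK cell-like cells, which kill without prior priming, were 5.11 and 4.45% untreated and 1.89 and 1.20% after doxorubicin. Epithelial (tumour)-like cells, which the CD45 sort should have removed, still made up 12.3 and 10.8% untreated and 6.89 and 6.16% after doxorubicin. Unnamed cells made up 35.2 and 20.5% untreated and 5.07 and 8.08% after doxorubicin. Most of these were cluster 5, a Ccl17, Ccl24, Chil3 and Ccr2 group with too few detected markers for a name (25.6 and 13% untreated against 2.91 and 6.28%), and cluster 17, a Ptn, Acta2 and Krt5 group (6.92 and 2.45% against 0.270 and 1.0%). Shares come from a magnetic CD45 sort and from libraries that differ in depth, and each class's share moves when another class grows.

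**Figure D1:**
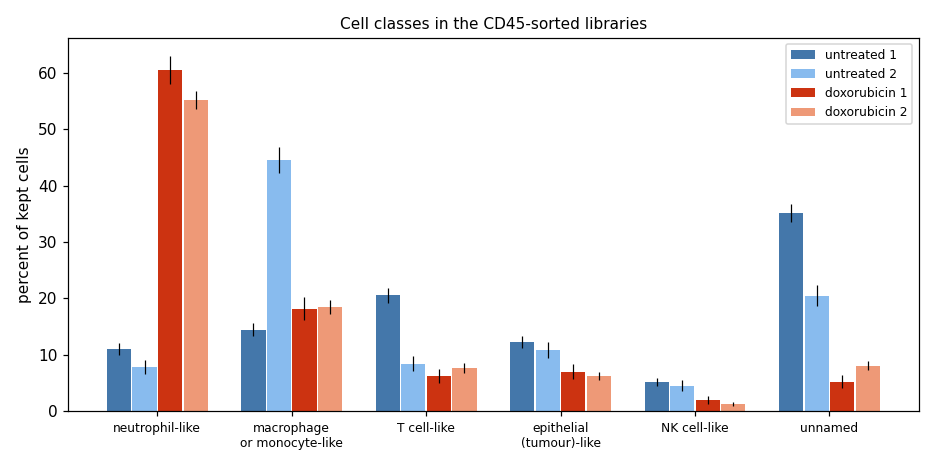
Percent of cells in each named class (vertical axis) in the 4 CD45-sorted libraries, 2 untreated and 2 at 48 h after doxorubicin, with exact Clopper-Pearson intervals. The neutrophil-like class takes 60.6 and 55.2% of the doxorubicin libraries and 10.9 and 7.79% of the untreated ones.

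Summing all barcodes of each CD45-sorted library asks which genes differed in the immune compartment as a whole. Il1f9, Stfa1, Stfa2, Mmp9, Saa3 and Chil1 were among the largest called rises. Il1f9, an interleukin-36 cytokine, rose by 5.26 log2 units (SE 0.379, n = 2 against 2, edgeR adjusted p = 0.0097), the protease gene Mmp9 by 4.73 (SE 0.361, adjusted p = 0.0097), the acute-phase gene Saa3 by 4.67 (SE 0.324, adjusted p = 0.0097) and Chil1 by 4.48 (SE 0.275, adjusted p = 0.0097). The stefin genes Stfa1 and Stfa2 rose by 5.11 and 5.07, though as near-identical copies they may split reads. The interferon-inducible GTPase gene Iigp1 changed by -3.23 (SE 0.449, adjusted p = 0.0237), the cytokine gene Ifng by -3.07 (SE 0.397, adjusted p = 0.0199), the mitotic cyclin gene Ccnb1 by -3.09 and the imprinted gene Mest by -3.04. In all, 875 of 16089 genes passed edgeR's threshold (514 rose and 361 fell), and 4315 had an unadjusted p under 0.05. Every library left out lowered the count, to 557 and 549 without untreated replicates 1 and 2 and to 372 and 404 without doxorubicin replicates 1 and 2. These sums mix cell classes whose shares differed, with the neutrophil-like class at 57.9% after doxorubicin and 9.37% untreated.

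Among gene lists in the summed libraries, genes of dividing cells fell and secreted inflammatory factors rose. The G2/M list had a median log2 change of -2.45, with 29 of 33 members fallen and 33 adjusted over the list alone (camera adjusted p = 2.34e-51, 0.166 with an estimated correlation), led by Cenpf, Cenpe and Top2a (-2.42, -2.71 and -2.25). The S phase list changed by -1.64, with 23 of 31 members fallen and 28 adjusted over the list alone (camera adjusted p = 1.13e-30, 0.111 with an estimated correlation), and homologous recombination genes by -1.62 (7 of 22, 16 alone, adjusted p = 2.21e-10, 0.146 with an estimated correlation). Senescence-associated secretory factors had a median of 1.30, with 16 of 46 risen and 28 risen with 1 fallen adjusted over the list alone (adjusted p = 3.96e-22, 0.111 with an estimated correlation), among them Igfbp6 (3.33) and the neutrophil-attracting chemokine gene Cxcl3 (4.14). MHC class II genes, which present antigen to CD4 T cells, had a median of -2.01 (5 of 12 fell, 11 alone, adjusted p = 4.1e-10, 0.405 with an estimated correlation), with their master regulator Ciita at -2.36. MHC class I genes had a median of -0.93 (7 of 24 fell, 13 alone, adjusted p = 4.1e-10, 0.527 with an estimated correlation), and interferon-gamma response genes of -1.44 (12 of 37 fell and 2 rose, 26 and 5 alone, adjusted p = 4.96e-12, 0.438 with an estimated correlation). Targets of p53, the DNA damage-activated transcription factor, had a median of 0.68 (11 of 41 rose and 2 fell, 22 and 2 alone, adjusted p = 2.21e-10, 0.166 with an estimated correlation), with Zmat3 at 2.11, Eda2r at 4.86 and the death receptor gene Fas at 2.03. NF-kB targets had a median of 0.84 (9 of 34 rose and 1 fell, 18 and 1 alone, adjusted p = 1.69e-10, 0.146 with an estimated correlation), and alternative macrophage activation genes of 1.14 (5 of 15 rose, 10 alone, adjusted p = 1.51e-10, 0.19 with an estimated correlation), led by Spp1 (3.14) and Gpnmb (2.87). Cholesterol synthesis genes had a median of -0.88 (8 of 22 fell, 17 alone, adjusted p = 1.69e-10, 0.146 with an estimated correlation) and ribosomal protein genes of -0.91 (4 of 21 fell, 18 alone, adjusted p = 4.1e-10, 0.146 with an estimated correlation). Within the neutrophil-like class, secretory factors and NF-kB targets were not called (medians -0.03 and -0.01, camera adjusted p = 0.504 and 0.124). In the macrophage- or monocyte-like class NF-kB targets were not called (-0.02, camera adjusted p = 0.914), while secretory factors were (0.77). Of these lists, the T cell-like class had a call for NF-kB targets alone (0.46), and the epithelial-like class for secretory factors alone (0.74).

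Smaller lists of the summed libraries passed less firmly, and each of the first 4 named here lost its call without 1 library. Lysosome genes had a median of 0.39 (3 of 30 rose, 7 alone, camera adjusted p = 0.000688, 0.592 with an estimated correlation and 0.118 without untreated replicate 1). Fibroblast markers had a median of 3.29 (1 of 13 rose, 1 alone, adjusted p = 0.000688, 0.592 with an estimated correlation and 0.0824 without doxorubicin replicate 2), endothelial markers of 1.11 (2 of 12 rose, 3 alone, adjusted p = 0.000688, 0.564 with an estimated correlation and 0.145 without doxorubicin replicate 1), and mesenchymal transition genes of 0.87 (1 of 19 rose, 4 alone, adjusted p = 0.0116, 0.31 with an estimated correlation and 0.0529 without doxorubicin replicate 2). Cytotoxic effector genes had a median of -1.02 (adjusted p = 0.00543, 0.592 with an estimated correlation), with Ifng fallen and the chemokine gene Ccl3 risen by 2.21. No call was made for type I interferon genes (median -0.44, adjusted p = 0.0387 with replicate number as a block), checkpoint ligand and immunoregulatory genes (0.02, with 2 risen and 2 fallen of 32), senescence and lamin genes (0.01), AP-1 factors (0.44), nucleic acid sensors (-0.25), Wnt targets (-0.35), luminal markers (0.09), basal markers (0.33), reference genes (-0.34), inhibitory receptors (-0.58), regulatory T cell genes (-0.54), naive and memory genes (0.06), costimulatory genes (-0.46) or inflammatory monocyte genes (0.53). Immune cell markers had a median of -0.29 while their test pointed up, also without a call.

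Testing within the neutrophil-like class asks whether these cells themselves differed after doxorubicin. Genes induced by interferon, a signal of viral and immune alarm, stood lower. Ifit2, which binds viral RNA, fell by 3.66 log2 units (SE 0.369, n = 2 against 2, edgeR adjusted p = 0.0334), from a mean of 166 to 12.9 CPM. Gbp3, a guanylate-binding protein gene of pathogen defence, fell by 3.46 (SE 0.376, adjusted p = 0.0334). These were the 2 of 8601 genes that passed, with 855 at an unadjusted p under 0.05 and 124 passing in DESeq2. Neither gene passed without the background filter, where the count was 0, and leaving out untreated replicates 1 and 2 or doxorubicin replicates 1 and 2 gave counts of 275, 64, 46 and 82. Type I interferon genes had a median of -1.46 with 1 of 31 fallen and 25 adjusted over the list alone (camera adjusted p = 5.27e-46, 0.403 with an estimated correlation). Interferon-gamma response genes had a median of -2.07 with 1 of 23 fallen and 18 adjusted over the list alone (adjusted p = 4.88e-37, 0.403 with an estimated correlation), and MHC class I genes of -1.52 with 0 of 23 and 15 (adjusted p = 1.54e-25, 0.403 with an estimated correlation). Single members short of the threshold were Ifi47 (-3.08), Gbp5 (-3.35), the peptide transporter gene Tap1 (-2.19) and the immunoproteasome gene Psmb9 (-1.91). RNA from other cells was not excluded as a source of these lower values.

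Other lists of the neutrophil-like class held no gene past edgeR's threshold over all genes. Ribosomal protein genes had a median of -1.15 (0 of 19 alone, camera adjusted p = 9.5e-12, 0.474 with an estimated correlation), S phase genes of -0.91 (1 of 17 alone, adjusted p = 9.08e-06, 0.44 with an estimated correlation), and nucleic acid sensing genes of -0.66 (4 of 12 fallen and 1 risen alone, adjusted p = 0.000133, 0.403 with an estimated correlation). Chemokine and effector genes of the cytotoxic list, including Ccl4 (-1.65), had a median of -0.87 (2 of 5 alone, adjusted p = 0.00274, 0.474 with an estimated correlation), a call lost without untreated replicate 2 (0.175) or doxorubicin replicate 1 (0.111). The p53 targets had a median of 0.39 (0 of 29 risen and 1 fallen alone, adjusted p = 0.0376, 0.44 with an estimated correlation), also lost without untreated replicate 2 (0.287) or doxorubicin replicate 1 (0.0867).

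Within the macrophage- or monocyte-like class, the same question showed Spp1, Mfge8 and Ccl17 among the largest called rises, and Dnase1l3, Iigp1 and Cdca3 among the largest falls. Spp1, which encodes osteopontin, rose by 3.17 log2 units (SE 0.496, n = 2 against 2, edgeR adjusted p = 0.0257), and Mfge8, a bridge for the uptake of dying cells, by 4.88 (SE 0.735, adjusted p = 0.0481). The chemokine gene Ccl17 rose by 4.05 (SE 0.545, adjusted p = 0.0282), Chst11 by 3.07, Dcstamp by 2.87, and Inhba, a subunit of activin, by 2.86 (SE 0.268, adjusted p = 0.00419). Ccl17 was also a leading gene of the unnamed cluster 5, a larger part of the untreated libraries, which was kept out of this class. Its rise thus covers only the cells named to the class. Dnase1l3, which digests extracellular DNA, changed by -3.76 (SE 0.594, adjusted p = 0.044), Klrb1b by -3.53, Iigp1 by -3.42 (SE 0.289, adjusted p = 0.00396) and the mitotic gene Cdca3 by -3.24. In total 395 of 10873 genes passed (142 rose and 253 fell), with 2103 at an unadjusted p under 0.05. Without untreated replicate 1 the count was 1107, without untreated replicate 2 it was 265, without doxorubicin replicate 1 it was 5 and without doxorubicin replicate 2 it was 0. DESeq2 split its calls more evenly, with 330 risen and 353 fallen. Different clusters held the class in the 2 groups. Untreated, cluster 6, with C1qc and Vcam1, held 63.1 and 49.5% of it and cluster 8, with mast cell protease genes and low UMIs, 12.4 and 46.9%. After doxorubicin, cluster 7, with Spp1, Mmp12 and Gpnmb, held 38.4 and 42.7% and cluster 22, with Ccl8, Folr2 and Cd163, 25.8 and 32.0%. Cluster 6 then held 19.4 and 15.2% and cluster 8 16.4 and 10.1%, so cluster 8 did not separate the groups.

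Antigen presentation and cell division lists followed the same directions in the macrophage- or monocyte-like class. MHC class II genes had a median of -1.83, with 8 of 9 fallen in both counts (camera adjusted p = 2.29e-15, 0.441 with an estimated correlation), Ciita at -2.12 and H2-DMa at -1.83. Interferon-gamma response genes had a median of -1.25 (8 of 31 fell, 18 alone, adjusted p = 4.34e-19, 0.523 with an estimated correlation), including Cxcl10, a T cell-attracting chemokine gene, at -2.24. MHC class I genes had a median of -0.89 (6 of 24 fell, 12 alone, adjusted p = 3.84e-10, 0.53 with an estimated correlation). Type I interferon genes, at -0.21, were not called (adjusted p = 0.982). The G2/M list had a median of -2.76 (30 of 33 fell, 32 alone, adjusted p = 1.47e-64, 0.441 with an estimated correlation), with Mki67 and Top2a both at -2.81, the S phase list of -1.86 (20 of 31, 29 alone, adjusted p = 1.83e-37, 0.441 with an estimated correlation) and homologous recombination genes of -1.99 (6 of 20, 15 alone, adjusted p = 3.51e-13, 0.523 with an estimated correlation). The p53 targets had a median of 0.77 (6 of 33 rose and 1 fell, 16 and 1 alone, adjusted p = 1.36e-11, 0.441 with an estimated correlation), with Zmat3 at 2.41 and Ephx1 at 2.60. Within clusters 6, 7 and 8 taken singly, p53 targets had medians of 0.90, 0.61 and 1.01, interferon-gamma genes of -1.14, -0.72 and -1.26, type I interferon genes of -0.50, -0.53 and -0.39, MHC class II genes of -0.99, -0.09 and -0.98, and G2/M genes of -2.84, -0.01 and -1.46. Cluster 22 had under 20 cells in a library and was left out, and cluster 7 had as few as 22 cells in a library.

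The remaining list calls of the macrophage- or monocyte-like class were smaller. Alternative activation genes had a median of 1.20 (1 of 15 rose, 4 alone, camera adjusted p = 5.85e-07, 0.632 with an estimated correlation), secretory factors of 0.77 (1 of 21, 1 alone, adjusted p = 0.000175, 0.523 with an estimated correlation) and lysosome genes of 0.38 (1 of 30, 3 alone, adjusted p = 0.000513, 0.653 with an estimated correlation), with Ctsd, a cathepsin gene, at 1.64. Ribosomal protein genes had a median of -0.73 (adjusted p = 6.19e-06, 0.632 with an estimated correlation). Mesenchymal transition genes, with Thbs1 at 1.72, had a median of 0.45 (adjusted p = 0.0229, 0.632 with an estimated correlation and 0.0903 without doxorubicin replicate 1). Cholesterol synthesis genes had a median of -0.41 (adjusted p = 0.0145, 0.653 with an estimated correlation, 0.174 without untreated replicate 2 and 0.145 without doxorubicin replicate 1). Inhibitory receptor genes had a median of -1.18, with Lag3 (-2.99) and Havcr2 (-1.34) fallen (adjusted p = 0.0168, 0.653 with an estimated correlation, 0.436 without untreated replicate 2 and 0.16 without doxorubicin replicate 2).

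Within the T cell-like class of the CD45-sorted libraries, no single gene passed, and the lists gave lower division genes beside higher type I interferon genes. Ifit3, an interferon-stimulated gene, stood 2.86 log2 units higher after doxorubicin (SE 0.414, n = 2 against 2, edgeR adjusted p = 0.081), the mitotic motor gene Cenpe changed by -1.40 and the cholesterol synthesis gene Fdps by -1.86, all short of the threshold. The checkpoint receptor genes Pdcd1 and Ctla4 were at -0.81 (adjusted p = 0.586) and -0.45 (adjusted p = 0.587). The clusters of the class differed too. Cluster 25, with histone genes and Top2a, held 18 and 27.2% of it untreated and 5.5 and 3.3% after doxorubicin, and cluster 14, with Ifit3 and Ifit1, 1.77 and 1.33% against 3.3 and 13.5%. In doxorubicin replicate 1 the shares of clusters 25 and 14 rest on 5 and 3 cells. edgeR called 0 of 8885 genes, with 807 at an unadjusted p under 0.05 and 31 called by DESeq2. Leaving out untreated replicates 1 and 2 or doxorubicin replicates 1 and 2 gave 79, 29, 15 and 5. The G2/M list had a median of -1.16 (29 of 33 fallen adjusted over the list alone, camera adjusted p = 1.36e-38, 0.284 with an estimated correlation), the S phase list of -0.75 (18 of 31 alone, adjusted p = 1.58e-22, 0.284 with an estimated correlation), cholesterol synthesis of -0.77 (7 of 21 alone, adjusted p = 7.02e-14, 0.284 with an estimated correlation) and homologous recombination of -0.65 (3 of 18 alone, adjusted p = 4.22e-06, 0.387 with an estimated correlation). Type I interferon genes had a median of 0.68 (6 of 27 risen alone, adjusted p = 2.57e-09, 0.483 with an estimated correlation and 0.211 without doxorubicin replicate 2), against -0.29 for interferon-gamma genes (adjusted p = 0.0837, not called). Naive and memory genes, with the homing receptor gene Ccr7 at 1.22, had a median of 0.56 (2 of 11 alone, adjusted p = 2.79e-05, 0.387 with an estimated correlation), Wnt targets, with Myc at 1.31, of 0.86 (3 of 6 alone, adjusted p = 1.65e-05, 0.387 with an estimated correlation), NF-kB targets of 0.46 (0 of 20 alone, adjusted p = 0.000139, 0.399 with an estimated correlation) and checkpoint and immunoregulatory genes, with Fas at 1.26 and Tnfsf4 at 1.69, of 0.32 (2 of 17 alone, adjusted p = 0.00087, 0.387 with an estimated correlation and 0.203 without doxorubicin replicate 2). Reference genes, with Gapdh at -0.74, had a median of -0.45 (2 of 11 alone, adjusted p = 0.0234, 0.428 with an estimated correlation, 0.136 without untreated replicate 2 and 0.0605 without doxorubicin replicate 1).

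Epithelial (tumour)-like cells carried through the CD45 sort gave the closest view of tumour cells with replicates. Doublets were not removed from these libraries, so droplets that held a tumour cell and an immune cell may be among them. The chemokine gene Cxcl5, which attracts neutrophils, rose by 7.80 log2 units (SE 0.722, n = 2 against 2, edgeR adjusted p = 0.00406), on 7 and 2 UMIs untreated against 190 and 776 after doxorubicin. The basal keratin gene Krt14 rose by 4.73 (SE 0.403, adjusted p = 0.000963), Anxa8 by 4.29, Fcgbp by 4.27, Chil1 by 4.15 and Ecm1 by 4.14. Mitotic genes fell most, with Ccnb1 at -4.04 (SE 0.287, adjusted p = 0.000819), Cdca3 at -4.00, Nusap1 at -3.88 and Cenpf at -3.74. The p53 targets Zmat3 (3.44, SE 0.24, adjusted p = 0.000819), Phlda3 (3.03), Ephx1 (2.56) and Gdf15 (2.79) rose. In total 950 of 11593 genes passed (368 rose and the rest fell), with 2901 at an unadjusted p under 0.05, and the count was 360 and 253 without untreated replicates 1 and 2. Different clusters held the class in the 2 groups. Cluster 0, with Igfbp5, Clu and Krt18, held 82.4 and 81.7% of it after doxorubicin and 51.1 and 25.3% untreated, while cluster 1, with Pbk and Cdc20, held 6.86 and 6.50% against 48.4 and 74.2%. Cluster 3 held the rest, 10.8 and 11.8% after doxorubicin (11 and 29 cells) and almost none untreated. Changes of single genes such as Krt14 were not read within clusters, so they may reflect this shift.

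Lists in the epithelial-like class pointed down for division and interferon response and up for p53 targets, and the difference from other classes was tested only for interferon genes. The G2/M list had a median of -3.29, with 33 of 33 fallen in both counts (camera adjusted p = 1.78e-93, 0.301 with an estimated correlation), the S phase list of -1.94 (24 of 31, 29 alone, adjusted p = 2.61e-41, 0.314 with an estimated correlation) and homologous recombination genes of -1.54 (11 of 22, 15 alone, adjusted p = 7.15e-10, 0.314 with an estimated correlation). The p53 targets had a median of 1.16 (18 of 37 rose and 1 fell, 24 and 2 alone, adjusted p = 3.72e-22, 0.301 with an estimated correlation). Interferon-gamma genes had a median of -2.19 (13 of 32 fell, 17 alone, adjusted p = 1.76e-18, 0.314 with an estimated correlation), with Batf2 at -3.35, type I interferon genes of -0.85 (4 of 32, 10 alone, adjusted p = 4.21e-07, 0.547 with an estimated correlation) and MHC class I genes, with Psmb9 at -2.49, of -0.97 (9 of 23, 19 alone, adjusted p = 1.47e-10, 0.314 with an estimated correlation). Within cluster 0 alone, the medians were -1.98 for G2/M, 1.16 for p53, -2.74 for interferon-gamma, -1.02 for type I interferon and -0.92 for MHC class I. Basal, secretory and luminal lists were not read within clusters, so a shift between clusters stays open for them. Basal markers had a median of 1.20 (2 of 10, 3 alone, adjusted p = 0.000134, 0.314 with an estimated correlation), secretory factors of 0.74 (3 of 10, 3 alone, adjusted p = 0.000351, 0.314 with an estimated correlation) and luminal markers, with Ly6d at 2.47, of 0.34 (1 of 19, 3 alone, adjusted p = 0.0307, 0.314 with an estimated correlation and 0.0609 without doxorubicin replicate 2). Ribosomal protein genes had a median of -0.78 (8 of 21, 17 alone, adjusted p = 1.69e-06, 0.314 with an estimated correlation), cholesterol synthesis genes, with Fdps at -1.98, of -0.73 (5 of 22, 12 alone, adjusted p = 1.61e-06, 0.314 with an estimated correlation) and reference genes, with Gapdh at -1.11, of -0.33 (1 of 11, 4 alone, adjusted p = 0.026, 0.345 with an estimated correlation and 0.068 without untreated replicate 2).

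**Figure D2:**
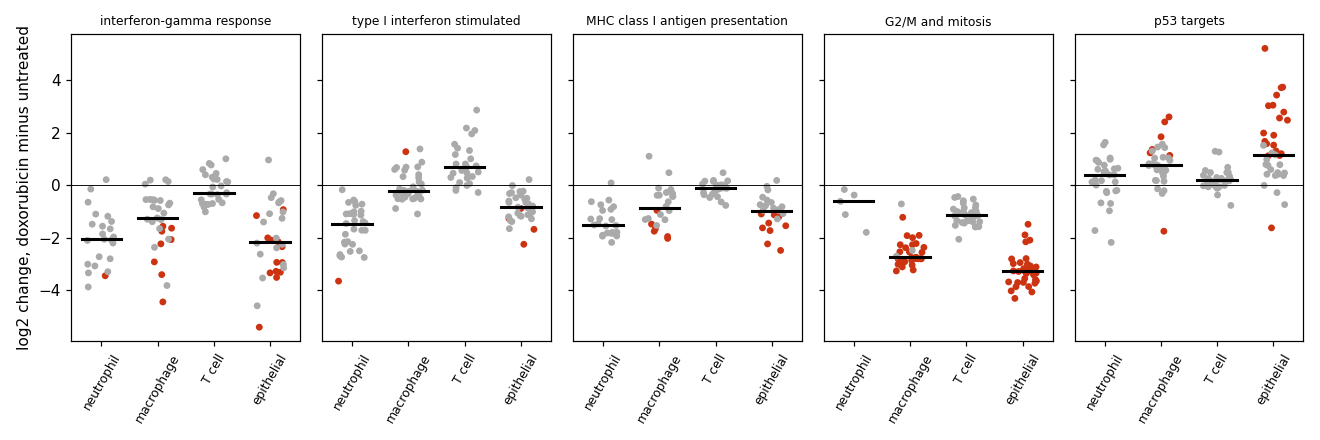
Log2 change, doxorubicin minus untreated, of each member of 5 gene lists in 4 cell classes of the CD45-sorted libraries, with red dots for genes past edgeR's threshold and a line at the list median. G2/M medians lie at -3.29 in the epithelial-like, -2.76 in the macrophage- or monocyte-like and -1.16 in the T cell-like class.

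The series title concerns immune checkpoint expression after chemotherapy, so the ligand genes Cd274 and Cd80 were read in 4 classes. Cd274 encodes PD-L1, the ligand of PD1, and Cd80 encodes a ligand of CTLA4 and CD28. In whole CD45-sorted libraries Cd80 stood 1.81 log2 units higher after doxorubicin (SE 0.368, n = 2 against 2, edgeR adjusted p = 0.0518) and Cd274 0.13 higher (SE 0.272, adjusted p = 0.804), neither past the threshold. Neutrophil-like cells held the most Cd274 of the classes compared, at 8.42 and 11.9 UMIs per 10000 untreated and 3.24 and 3.82 after doxorubicin, a change of -1.69 (SE 0.378, adjusted p = 0.177, 0.264 without the background filter). Macrophage- or monocyte-like cells held 1.42 and 1.78 Cd274 UMIs per 10000 untreated and 1.12 and 1.32 after doxorubicin (adjusted p = 0.357). Their Cd80 level was 0.182 and 0.353 per 10000 untreated and 0.651 and 0.700 after doxorubicin, a change of 1.30 (SE 0.318, adjusted p = 0.0771, 0.107 without that filter). In the neutrophil-like class Cd80 was 1.46 and 0.981 untreated and 1.90 and 1.17 after doxorubicin (adjusted p = 0.899). Epithelial-like cells held 0.103 and 0.139 Cd274 UMIs per 10000 untreated and 0.123 and 0.0621 after doxorubicin, and 0.0176 and 0.00938 Cd80 UMIs against 0.0688 and 0.0303 (1.56 log2 units, SE 0.601, n = 2 against 2, edgeR without the background filter, unadjusted p = 0.032 and adjusted p = 0.16). T cell-like cells held 0.269 and 0.552 Cd274 UMIs untreated and 0.318 and 0.585 after doxorubicin, and 0.0305 and 0.0971 Cd80 UMIs against 0.0578 and 0.108 (edgeR adjusted p = 0.933 and 0.832, also without that filter). Both classes lay far under the neutrophil-like level, where free RNA from other cells was not excluded.

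In the CD4/8-sorted libraries, the 48 h library against the untreated one asks how the T cell-like class differed after doxorubicin. The regulatory genes Foxp3 and Il10 and the granzyme genes Gzma and Gzmb were lower, and the exhaustion genes Pdcd1, Tox and Havcr2 higher, while the checkpoint receptor gene Ctla4 was lower. Foxp3, the defining factor of regulatory T cells, was at 0.431 UMIs per 10000 untreated and 0.138 at 48 h, a log2 ratio of -1.64 (exact interval -1.81 to -1.48). Il10, an immunosuppressive cytokine gene, stood at -1.96, the receptor gene Klrg1 at -2.26, and the granzyme genes Gzma and Gzmb at -2.06 and -1.85. Ctla4 was at 1.60 against 2.77 per 10000 (-0.79, -0.84 to -0.74). Pdcd1, which encodes PD1, was higher by 0.61 (0.54 to 0.68), the exhaustion regulator Tox by 0.94 and Havcr2 by 1.05. The genes with the highest ratios were Gzmf (4.26), Fam178b (3.51), Batf3 (3.12), Dscam (3.04), Klri2 (2.85) and Ttn (2.84), where granzyme copies may split reads. The histone genes Hist1h3b and Hist1h2ag were at -1.85 and -1.71, also near-identical copies. With each cell thinned to 2000 UMIs, 9.37% (Clopper-Pearson 8.19 to 10.7%) of untreated and 2.46% (1.98 to 3.02%) of 48 h cells had a Foxp3 UMI. Before thinning these were 17.3 and 5.17% at median depths of 7893 and 6059 UMIs. Epithelial-like cells of the 6 libraries, which should lack Foxp3, gave 0 to 0.367% after thinning, at median depths of 17830 to 41230. Before thinning they gave 0.826 to 2.755%. Because these cells are deeper, thinning can take more free RNA from them than from T cell-like cells. Their thinned shares may thus understate the background of the T cell-like class. The inhibitory receptor list had a median of 0.61 (10 of 11 higher, above 100% of matched random lists), the regulatory list of -0.53 (11 of 13 lower, above 0%) and the G2/M list of -0.59 (33 of 33 lower, above 0%). The replicated T cell-like class of the CD45-sorted libraries, also at 48 h, gave no call for the first lists. Inhibitory receptors had a median of -0.04 there (5 higher and 6 lower, camera adjusted p = 0.695). Regulatory genes had one of -0.13 while their test pointed up (adjusted p = 0.596). Pdcd1 was lower there without a call, while the G2/M list was lower in both. In the CD4/8-sorted libraries, the Foxp3 cluster 13 held 19.7% of the class untreated and 5.34% at 48 h, and cluster 10, with Prf1, Ifng and Cd8a, 2.38 and 10.9%.

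The antibody arms ask how T cells differed when checkpoint blockade followed doxorubicin, and all 3 are set against the same IgG library. With anti-PD1, interferon-stimulated genes and the effector genes Prf1 and Ifng were lower than with IgG. Prf1, which encodes the pore-forming protein perforin, was at 0.330 UMIs per 10000 against 2.71, a log2 ratio of -3.04 (exact interval -3.15 to -2.93). Ifng was at 1.27 against 4.26 (-1.75), the interferon-stimulated gene Usp18 at -2.43 and Cd8a at -0.84. The transcription factor gene Batf3 was higher by 4.44 (3.53 to 5.52), followed by Bex1 (2.71), Mt3 (2.19), Igf2bp3 (2.11), Cd70 (1.80) and Sdhaf1 (1.75). The lowest ratios after Prf1 were those of Trav16n (-2.68), Glp1r (-2.68), Upk1a (-2.65) and Art2b (-2.60), where receptor segments such as Trav16n share sequence and may split reads. Trav16n and Art2b were also among the lowest with anti-CTLA4, and Upk1a with both antibodies, all against the same IgG library. For these genes a trait of that library and an effect of the antibodies cannot be told apart. The type I interferon list had a median of -1.02 (27 of 27 lower, above 0% of matched random lists), the interferon-gamma list of -0.60 (27 of 28 lower) and the NF-kB list of 0.37 (16 of 21 higher). Pdcd1 was at -0.25 (-0.33 to -0.17), but at 0.0059 at Leiden resolution 2, and Ctla4 was at 0.26 (0.21 to 0.31). Foxp3 was at 0.304 against 0.275 per 10000, a ratio of 0.14 (-0.01 to 0.30) whose interval includes 0. Cluster 14 held 1.65% of the class here and 7.08% with IgG, and cluster 10 9.94 and 16.9%. Cluster 12, a Gzma, Ccl5 and Tcrg-C2 group left out of the class because more of its top genes marked another class, was 6.59% of this library and 16.7% of the IgG one. With that cluster counted in the class, Gzma turned from a ratio above 0 to -0.18.

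With anti-CTLA4, Foxp3 and Il10 were lower than with IgG and the cytokine gene Il5 higher, while the regulatory genes Il2ra (0.47) and Nrp1 (0.56) were higher. Foxp3 was at 0.0423 UMIs per 10000 against 0.275, a log2 ratio of -2.70 (exact interval -2.98 to -2.43), Il10 at -2.63 (-3.03 to -2.24), Klrg1 at -2.61 and the folate receptor gene Izumo1r at -1.71. Cells with a Foxp3 UMI after thinning were 0.628% (Clopper-Pearson 0.335 to 1.07%) against 5.13% (4.23 to 6.16%), and 2.10 against 11.3% before thinning at median depths of 11430 and 9890. Epithelial-like cells of these libraries gave 0.893 and 1.38% before thinning. Il5, a cytokine gene of eosinophil growth, was higher by 3.34 (2.62 to 4.14), Batf3 by 5.47 (4.58 to 6.54), Havcr2 by 1.0 and Pdcd1 by 0.70 (0.63 to 0.76), with Ctla4 at -0.08 (-0.13 to -0.03). Prf1 was at 4.46 against 2.71 per 10000, a ratio of 0.72. The segments Trav9n-4 (6.87), Trbv29 (3.57), Trav6-7-dv9 (3.39) and Trbv2 (3.33) were among the highest, and Trav16n (-2.69), Art2b (-2.41) and Ncmap (-2.07) among the lowest. With 1 library per group, the receptor segments of a single sample cannot be told from an effect of the antibody. Division lists were slightly higher, with G2/M at 0.26 (30 of 33 higher) and S phase at 0.27 (28 of 31 higher), while type I interferon genes were at -0.28 (22 of 27 lower). Cluster 10 held 30.9% of the class here and 16.9% with IgG, and cluster 12 made up 15 and 16.7% of the libraries.

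With both antibodies, Foxp3 was at 0.138 UMIs per 10000 against 0.275 with IgG, a log2 ratio of -0.99 (exact interval -1.16 to -0.82), and Il10 at -2.55 (-2.93 to -2.19). After thinning, 1.89% (Clopper-Pearson 1.39 to 2.5%) of cells had a Foxp3 UMI, against 5.13%. Il5 was higher by 3.20 (2.48 to 4.00) and Il13, another type 2 cytokine gene, by 2.20 (2.02 to 2.38). Batf3 was higher by 4.03 (3.13 to 5.12), Trbv2 by 3.34, the heat shock gene Hspa1b by 2.13, Fam124b by 2.13, Pdcd1 by 0.86 (0.80 to 0.93) and Ctla4 by 0.20 (0.16 to 0.25), while Prf1 was at -0.84. Gzmd at -2.13 and Cxcl13 at -1.94 were among the lowest beside Tmem108 (-2.05), Cmpk2 (-1.90) and Upk1a (-1.86). Gzmd turned to 3.98 and 3.85 at Leiden resolutions of 0.5 and 2, and Cxcl13 to 1.74 without the cells with most UMIs. Type I interferon genes had a median of -0.84 (27 of 27 lower), NF-kB targets of 0.59 (19 of 21 higher) and AP-1 factors of 0.31 (7 of 7 higher). Cluster 10 held 29.0% of the class and cluster 12 made up 12.7% of the library.

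**Figure D3:**
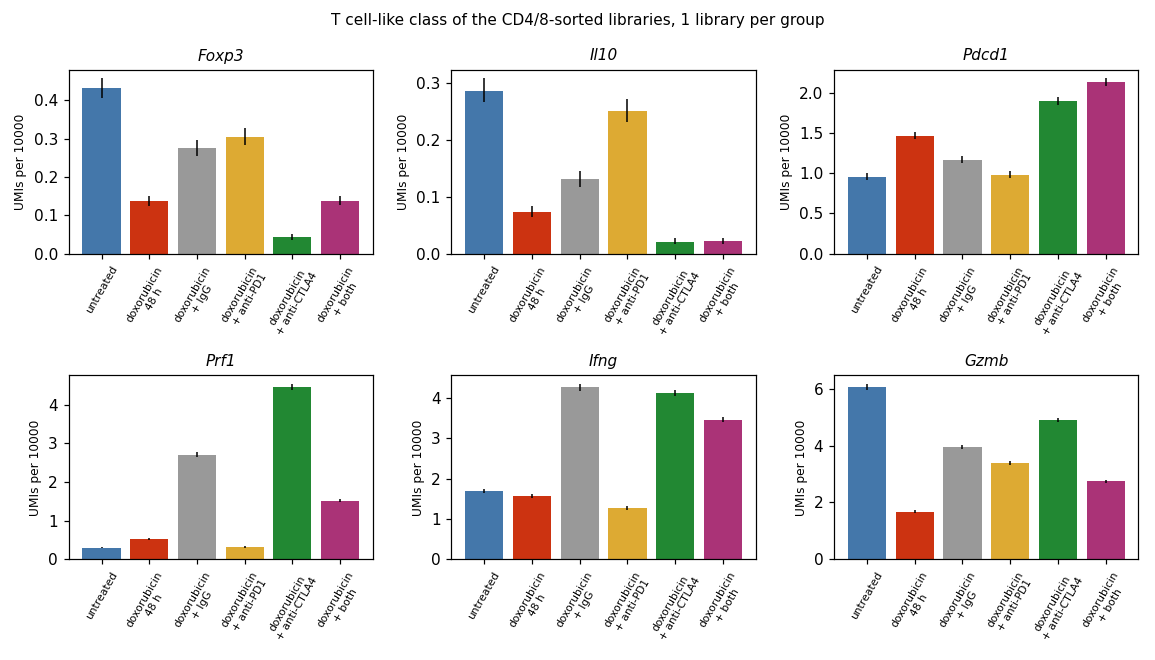
UMIs per 10000 of Foxp3, Il10, Pdcd1, Prf1, Ifng and Gzmb in the T cell-like class of the 6 CD4/8-sorted libraries, 1 library per group, with exact Poisson intervals. Foxp3 lies at 0.431 untreated, 0.138 at 48 h, 0.275 with IgG, 0.304 with anti-PD1, 0.0423 with anti-CTLA4 and 0.138 with both antibodies.

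The T cell lists ask whether such genes moved together in the antibody arms. Inhibitory receptor and exhaustion genes were at -0.25 with anti-PD1, 0.14 with anti-CTLA4 and 0.20 with both antibodies, against IgG. Cytotoxic effector genes were at -0.11 at 48 h against untreated, and at -0.11, 0.05 and -0.06 in the same 3 arms. Regulatory T cell genes were at 0.23 (10 of 13 higher), -0.16 (9 of 13 lower) and -0.14. Naive and memory genes were at 0.16 at 48 h, and at -0.59, -0.46 and -0.49 in the arms. Costimulatory genes were at -0.18 at 48 h, and at -0.21, -0.08 and 0.16. With anti-PD1 the sign of the inhibitory receptor list turned at another clustering resolution (0.22 at resolution 0.5), as did that of the cytotoxic list (0.05). With anti-CTLA4 the cytotoxic list turned when cluster 12 joined the class (-0.09), and with both antibodies it turned at resolution 2 (0.09) and without the cells with most UMIs (0.02).

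The pooled table of tumour single cells shows which classes carried the checkpoint ligand genes in unsorted tumour tissue. Its 3970 kept cells were 27.9% epithelial (tumour)-like, 23.6% neutrophil-like, 18.7% macrophage- or monocyte-like, 10.3% T cell-like and 13.1% unnamed. Cd274 was at 2.98 UMIs per 10000 in neutrophil-like, 1.0 in dendritic-like, 0.491 in macrophage- or monocyte-like, 0.418 in T cell-like and 0.0413 in epithelial-like cells. Cd80 was at 1.60, 0.558 and 0.199 in the first 3 of these and at 0.00334, or 8 UMIs, in epithelial-like cells. Wnt1, the transgene's oncogene, gave 128 UMIs in epithelial-like and 52 in unnamed cells, 1 in macrophage- or monocyte-like cells and 0 in neutrophil-like cells. Cdkn1a, a p53 target that halts the cell cycle, was at 22.6 UMIs per 10000 in neutrophil-like and 3.96 in epithelial-like cells. The table does not say which cells came from the treated tumour, so treated and untreated tumours were not compared.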

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

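The tests on the CD4/8-sorted neutrophil share, on free RNA and on the combination library were chosen after the results were seen, as were all comparisons of cell classes with each other. The 3 patterns here concern neutrophils, interferon genes and regulatory T cells.

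After doxorubicin, interferon gene lists stood higher against untreated in T cell-like cells than in other classes of the same CD45-sorted libraries. Type I interferon genes, such as Ifit3, had a median log2 change of 0.68 in T cell-like cells against -1.70 in neutrophil-like, -0.21 in macrophage- or monocyte-like and -0.95 in epithelial-like cells. The interaction gave adjusted p = 1.51e-73, 9.96e-09 and 9.66e-32 (limma camera on an edgeR fit, 6 tests), and 0.17, 0.287 and 0.17 with an estimated correlation, so none held under that choice. Interferon-gamma genes, such as Gbp3, had medians of -0.03 in T cell-like against -2.08 in neutrophil-like cells (adjusted p = 8.7e-30, 0.17 with an estimated correlation), and of -0.29 against -0.89 in macrophage- or monocyte-like (1.49e-09, 0.287) and -2.13 in epithelial-like cells (5.38e-22, 0.17). Over the 4 pairs of a doxorubicin and an untreated library, type I medians ran from -0.0012 to 1.01 in T cell-like, from -0.25 to -0.02 in macrophage- or monocyte-like, from -1.39 to -0.21 in epithelial-like and from -1.74 to -1.19 in neutrophil-like cells. Interferon-gamma medians ran from -0.53 to 0.04, -1.76 to -0.74, -2.60 to -1.22 and -2.65 to -1.25 in the same order. The T cell-like call rests on doxorubicin replicate 2 (adjusted p = 0.211 without it), where cluster 14, with Ifit3 and Ifit1, held 13.5% of the class against 1.33 to 3.3% in the other 3 libraries.

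Between macrophage- or monocyte-like and neutrophil-like cells, 75 of 9655 genes changed by different amounts (edgeR interaction, 919 at an unadjusted p under 0.05). The activin gene Inhba changed by 2.86 in the former and -2.21 in the latter (difference 5.16, SE 0.399, adjusted p = 0.000473), Chst11 by 3.07 and -0.12, and Cmpk2, a nucleotide kinase gene of the interferon response, by 1.28 and -2.51. None of the 5 genes named in both classes was among the 75 (edgeR, 0 of 5).

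For the interferon pattern, RNA shared by all classes of a library can be at most the UMIs per cell of the T cell-like class, which were taken off the untreated libraries alone. The interferon-gamma median of epithelial-like cells then stayed at -0.513 or lower in each pair, which argues against free RNA as the whole cause there. Doublets, which were not removed, are not covered by this ceiling. For type I genes in epithelial-like cells the pairs ran from -1.02 to 0.323. Before the UMIs were taken off, this calculation, unlike that of the pairs given above, had them from -1.24 to 0.0734. The sign was thus not the same in every pair even then. With the UMIs taken off, the pairs in neutrophil-like cells ran from -0.772 to 0.839 (type I) and from 1.68 to 3.92 (interferon-gamma). In macrophage- or monocyte-like cells they ran from -0.261 to 0.367 (interferon-gamma). For these, free RNA and a change in the cells cannot be told apart under so loose a ceiling. The interferon-gamma medians within macrophage clusters 6, 7 and 8 were -1.14, -0.715 and -1.26 (pairs from -1.76 to -0.44, -0.87 to -0.43 and -1.28 to -1.02) against -1.30 in the whole class, which argues against a shift between clusters as the whole cause and leaves it open as a part. Cluster 22, with 25.8 and 32.0% of the class after doxorubicin, had under 20 cells in a library and was not read. Cluster 7 had as few as 22 cells in a library. A biological explanation, a lower interferon signal in myeloid and tumour cells after doxorubicin, may hold but was not tested on its own.

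The higher share of neutrophil-like cells after doxorubicin might reflect low-UMI neutrophils lost from the untreated libraries. Among cells with 2000 or more UMIs the lowest doxorubicin share was still 5.34 times the highest untreated one, which argues against depth as the cause. A different yield of the CD45 sort stays open. In the CD4/8-sorted libraries, neutrophil-like cells were 29.7% of neutrophil- and macrophage-like cells at 48 h against 15.9% untreated, but with 1 library each, and the 2 untreated CD45-sorted libraries alone differed as much (43.2 and 14.9%). All these percentages leave out the unnamed cluster 5, so they depend on how that cluster is counted. An influx of neutrophils, or a loss of the other cells, stays open too.

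The low Foxp3 level in the anti-CTLA4 library could come from depth or from a fault of that library. With each cell thinned to 2000 UMIs, 0.628% of T cell-like cells had a Foxp3 UMI against 5.13% with IgG. Thinning was a weak test, because the anti-CTLA4 cells were the deeper ones (median 11430 against 9890 UMIs). Their share before thinning was already lower (2.10 against 11.3%), though greater depth would raise it, which argues against depth. A fault of this library stays open. The combination library, which also had anti-CTLA4, was at 0.138 Foxp3 UMIs per 10000 against 0.275 with IgG, but both arms share 1 IgG library and the 48 h library without antibody was also at 0.138. Loss of regulatory T cells under anti-CTLA4 is a hypothesis that stays open.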

How the results depend on the processing

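Alternatives within cell classes, for gene lists, T cell values, shares and the pooled table were chosen after the data were seen, and those for genes of the whole CD45-sorted libraries and for barcodes of the T cell libraries before. Where values moved, the cause was not tested, apart from fits without a library, which had fewer samples and assume that the lone library of a group varies like the others.

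Of the genes named in the whole library, 52 were called, 48 stayed called under each alternative that kept all libraries and 26 also with each library left out. For the macrophage- or monocyte-like class these numbers were 33, 19 and 0, for the epithelial-like class 40, 26 and 24, and for the neutrophil-like class 2, 0 and 0. No called gene reversed. Among uncalled ones, Cd274 in the whole library turned to -0.18 without untreated replicate 1 (0.51 at most with a library left out), and Cd80 in the neutrophil-like class to -0.20 at resolution 2, -0.03 without untreated replicate 2 and -0.32 without doxorubicin replicate 1 (0.58 at most). Over all named genes and alternatives, 2065 values kept direction and side of the threshold, 262 newly passed, 215 no longer passed and 4 reversed.

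Counts of called genes moved with the fit. In the whole library the count of 875 became 2504 with DESeq2, 1950 with no low count filter, 1416 with replicate number as a block, and 372 to 557 with a library left out. It was 880 with 1000 or more UMIs per barcode and 879 with RLE. The files hold no barcode under the main limit of 500 UMIs, so the fit to all barcodes repeats the main one and tests nothing, though its values are among the 2065 that kept. In the neutrophil-like class the 2 calls became 114 at resolution 2, 0 without the background filter (0 of all genes in edgeR), 124 with DESeq2, 227 with no low count filter, 666 with the block and 46 to 275 with a library left out. In the macrophage- or monocyte-like class 395 became 634 and 94 at resolutions 0.5 and 2, 683 with DESeq2, 1150 with no low count filter, 765 with the block and 0 to 1107 with a library left out. In the T cell-like class 0 (edgeR, 807 at an unadjusted p under 0.05) became 124 without the cells with most UMIs, 9 and 11 at resolutions 0.5 and 2, 31 with DESeq2, 172 with no low count filter, 1 with the block and 5 to 79 with a library left out. In the epithelial-like class 950 became 578 without the cells with most UMIs, 2058 with no low count filter, 1751 with the block and 253 to 963 with a library left out. The block pairs libraries that share only a replicate number. Across genes, the difference between replicates 1 and 2 of the untreated group correlated with that of the doxorubicin group at r of 0.225 to 0.392. The main fit does not model this shared part.

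List calls in the 5 comparisons numbered 17, 8, 14, 10 and 13 (whole library, then neutrophil-, macrophage- or monocyte-, T cell- and epithelial-like classes). None held with an estimated correlation (camera, adjusted p of 0.111 to 0.653), and fry, which asks whether genes of a list move one way, called 7 of the 17 and 0 of the others, and 1 list that camera did not call, senescence and lamin genes in the T cell-like class (0.0431). With the block 17, 8, 14, 10 and 13 held, and 9 uncalled lists gained a call. These were type I interferon genes in the whole library (0.0387), p53 targets and cytotoxic genes in the T cell-like class (0.0448 and 0.0254), NF-kB targets in the epithelial-like class (0.0247), and in the neutrophil-like class mesenchymal (0.00855), inhibitory receptor (0.00105), regulatory (0.0102), costimulatory (0.000777) and alternative activation genes (0.00945). Of the called lists, 13, 6, 11, 7 and 11 held with every library left out in turn. Over all these alternatives the highest adjusted p of a called list was 0.592, 0.474, 0.653, 0.483 and 0.547, and the lowest 7.67e-58, 1.93e-50, 2.96e-68, 5.11e-40 and 6.14e-104.

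Neutrophil-like shares moved to 51.2 and 50.5% in doxorubicin replicates 1 and 2 and 6.4% in untreated replicate 2 at resolution 2. Among cells with 2000 or more UMIs they moved to 52.1% in doxorubicin replicate 2 and 9.76% in untreated replicate 1. The other 11 shares stayed within their intervals.

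T cell list medians depended on which cells were in the class. At resolution 0.5 they moved, at 48 h against untreated, to -0.65 for regulatory, 0.21 for naive and memory and -0.22 for costimulatory genes. With anti-PD1 they moved to 0.22 for inhibitory receptors, 0.0501 for cytotoxic, 0.29 for regulatory and -0.71 for naive genes, with anti-CTLA4 to -0.24 for naive genes, and with both antibodies to -0.0175 for cytotoxic, -0.27 for regulatory, -0.37 for naive and 0.20 for costimulatory genes. At resolution 2 the 48 h naive median was 0.25. With anti-PD1 the medians were 0.0059 for inhibitory receptors, 0.35 for regulatory and -0.69 for naive genes, with anti-CTLA4 0.14 for cytotoxic and -0.40 for naive genes, and with both antibodies 0.45 for inhibitory receptors, 0.0888 for cytotoxic and -0.61 for naive genes. Without the cells with most UMIs the naive median was 0.20 at 48 h and -0.42 with both antibodies, where cytotoxic and costimulatory genes were at 0.0180 and 0.21. With cluster 12 in the class, anti-PD1 gave -0.39 for inhibitory receptors, -0.30 for cytotoxic, -0.50 for naive and -0.16 for costimulatory genes. Anti-CTLA4 gave 0.0186, -0.0900 and -0.10 for inhibitory receptors, cytotoxic and regulatory genes, and both antibodies 0.16, -0.33, -0.39 and 0.20 for inhibitory receptors, cytotoxic, naive and costimulatory genes. Of 100 such values for the 5 T cell lists 64 stayed within their interval and 36 did not, against 316 and 84 for other lists and 974 and 381 for genes.

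In the pooled table the T cell-like share was 1.31% at resolution 0.5 in place of 10.3%, and the epithelial-like share 31.9 and 33.6% at resolutions 0.5 and 2. The alternatives meant for the bulk and tumour comparisons were not run, because those comparisons were not made. With 1000 or more UMIs per barcode the T cell libraries kept 3514 to 7806 barcodes. Depth limits genes with few UMIs. Neutrophil-like cells of the pooled table had a median of 3182 UMIs against 17520 in epithelial-like ones.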

Other observations

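Genes of perforin and interferon-gamma differed widely between the 6 CD4/8-sorted libraries in the T cell-like class. The values here, chosen after they were seen, are UMIs per 10000 in 1 library each. Prf1 was at 0.306 untreated and 0.534 at 48 h after doxorubicin, then at 2.71 with IgG, 0.330 with anti-PD1, 4.46 with anti-CTLA4 and 1.52 with both antibodies. Ifng, the main effector cytokine gene of T cells, was at 1.70, 1.57, 4.26, 1.27, 4.12 and 3.45 in the same order. Gzmb was at 6.05, 1.68, 3.96, 3.38, 4.90 and 2.74, and Gzma at 11.5, 2.76, 5.62, 7.65, 10.2 and 4.66. The IgG library thus set a high baseline of Prf1 and Ifng for all 3 antibody ratios.

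Batf3, a transcription factor gene known best from dendritic cells, was rare in every library and rarest with IgG. It was at 0.0105 untreated, 0.0910 at 48 h, 0.00384 with IgG, 0.0833 with anti-PD1, 0.171 with anti-CTLA4 and 0.0630 with both antibodies. Il10 was at 0.286, 0.0736, 0.131, 0.25, 0.0211 and 0.0222 in that order. The large Batf3 ratios against IgG in all 3 arms share that 1 low value.

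Neutrophil-like cells also passed the CD4/8 sort. As a percent of neutrophil- and macrophage-like cells they were 11.6% with IgG, 9.19% with anti-PD1, 8.5% with anti-CTLA4 and 20.4% with both antibodies (Clopper-Pearson 13.4 to 29.0%), against 77.0 and 75.0% in the CD45-sorted doxorubicin libraries and 43.2 and 14.9% in the untreated ones. Epithelial-like cells made up 9.46% of the untreated, 20.6% of the 48 h, 6.00% of the IgG, 18.7% of the anti-PD1, 6.50% of the anti-CTLA4 and 3.42% of the combination library. T cell-like cells were 59.2, 48.9, 59.8, 44.8, 60.9 and 73.0% of the same libraries.

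In the pooled tumour table, the p53 targets Mdm2 and Cdkn1a were higher in neutrophil-like cells than in the other classes named here. Mdm2, which encodes the inhibitor of p53, was at 2.26 UMIs per 10000 there, against 0.460 in T cell-like and 0.296 in dendritic-like cells. Cdkn1a was at 5.34 in dendritic-like, 4.25 in macrophage- or monocyte-like and 1.18 in T cell-like cells. Which of these cells came from the treated tumour is unknown.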
